A study of Mus musculus with 4 samples.

How the data were processed

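Total RNA of 4 mouse samples was labelled with Cy3 from 0.25 ug each and hybridised to 1-colour Agilent whole-genome arrays. One sample, called Mixture, pooled equal masses of RNA from heart, kidney, thymus, spleen, liver, lung and day 11 embryo of Swiss Webster mice. The other 3 were neural progenitor cell (NPC) lines, each grown from a different embryonic stem cell line: NS21 and NSEB5-2C, which have the same strain label, and NS195R, which has another. NPC replicate 1 is NS21, replicate 2 is NS195R and replicate 3 is NSEB5-2C. Each line was hybridised once, so the spread between NPC arrays holds differences between lines together with technical error, and p-values measure that spread.

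The spot intensity values were made by Agilent Feature Extraction 9.5.3.1, per the file headers, which subtracted background and gave a processed signal and quality flags for each spot. The deposited value table held the same processed intensity at all 45018 features, so that it offered no other scale, centring or direction. Columns of other samples in that table numbered 0. All 4 arrays lay on 1 slide and came from 1 scan, so neither could be tested as a batch.

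Of the features, 43379 were not controls and formed 41174 probes. Processed signals were taken to log2 and each array's percentile 75 over non-control spots was subtracted. Spots flagged as non-uniform or as population outliers were left out, the 10 copies of each of 245 repeated probes were averaged, and 19 probes without a value on every array were dropped. Current symbols came from the RefSeq transcript for 22951 probes, from a listed transcript for 44, from the symbol for 6659 and from a synonym for 3078, with the gene table of assembly GRCm38.p6, and 8442 probes kept the name in the files. The genome build of the probe positions is not given in the sources used here. For each of 27658 genes or transcripts the probe with the highest mean over the arrays was kept, and the 19822 well above background on at least 1 array were tested, of which 15400 had a gene symbol. Of 6925 genes with more than 1 such probe, 353 had probes at least 1.5-fold higher and at least 1.5-fold lower at the same time. For 31 genes the kept probe was not well above background in Mixture while another probe was.

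The NPC lines were compared with Mixture with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The residual degrees of freedom were 2 and the prior added 1.33. The single Mixture array was assumed to vary like the NPC lines. Each line was compared with the other lines in the same way, and genes at least 2-fold from both were counted without a test. The study's own rule of size asked for at least 1.5-fold over Mixture in NSEB5-2C and in NS195R or NS21, and here also for signal well above background in those lines. The study picked transcription factors by Gene Ontology terms. Here 47 families of gene symbols replaced them. Their share was set beside other genes with Fisher's exact test and beside 10000 random lists matched on mean level in 20 bins. The same number of random lists was drawn for each of 27 gene lists. Because the line ratios share the Mixture array, 100 sets of unchanged lines were simulated with the spread between lines.

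Where a probe was not well above background on any array of a group, the ratio is a bound, written as at least N-fold: the brighter group's mean against, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The limma tests, gene lists, naming rule and most alternatives were fixed before the data were examined, and choices made later are said to be so where they appear. The rule named the 10 genes with the largest and the 10 with the smallest ratio among called genes measured on all arrays and at least 1.5-fold in every line. It also named the 15 selected transcription factors with the largest ratio and those that had only a bound and belonged to a list. Further names were up to 4 members per list with the largest change, members against a list's majority, the 5 genes farthest each way per line, and patterning and Hox genes at least 2-fold apart between lines. Some genes that the rule names are not reported here, and counts and medians of lists include them.

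The fits were tested on simulated data for the same 19822 genes. With 200 genes changed, the median error of the NPC ratio was 0.00313 on the log2 scale, and limma called 0 of 50 genes at each log2 size of 1, 2, 4 and 8. With many genes changed, it called 28 of 1537 at a log2 size of 1, 310 of 1537 at 2, 1125 of 1536 at 4 and 1396 of 1536 at 8, with 111 false calls. For NS195R against the other lines, simulated only with 200 genes changed, it called 0 of 50 at each size. Alternatives covered background correction with normexp and offset 50, quantile and median scaling, the filter on dim probes, the probe chosen per gene, the variance prior, the fold and lines of the rule, and leaving out each line.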

Results

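Gene expression was measured on 4 arrays: 1 of Mixture, a pool of RNA from 6 adult tissues and day 11 embryo, and 3 of neural progenitor cell lines. Of 43379 non-control spots, 26840 were well above background for Mixture, 24523 for NS21, 25690 for NS195R and 23983 for NSEB5-2C. Saturated spots numbered 0 on each array. The median SD of repeated probes within an array lay between 0.0583 and 0.0696 on the log2 scale. The number of arrays limits the precision of every comparison. No NPC line has the Swiss Webster strain of Mixture, so strain and cell type cannot be told apart in any ratio to Mixture.

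Markers of the pooled tissues were present in Mixture and low or not measurable in the NPC lines. This comparison also checked a conflict in the labels, since 1 label of the Mixture sample names a doxycycline-treated NPC line. All 67 measured markers of heart, kidney, thymus, spleen, liver and lung were well above background in Mixture, and 44 of them were not in any NPC line. With limma, 51 of the 67 were lower in the NPC lines. Without any 1 of the lines, members of all gene lists past the limma test numbered 0.

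The plasma protein gene Alb was at least 12880-fold lower in the NPC lines (limma adjusted p = 0.00846, lower in 3 of 3 lines), and all 12 measured liver markers fell by both adjustments. Nppa, which encodes a heart hormone, was at least 5133-fold lower, and 7 of 12 heart markers fell, or 11 adjusted over the list alone. Umod, a kidney tubule gene, was at least 3104-fold lower among 10 of 12 kidney markers that fell, or 12 adjusted over the list alone. The airway gene Scgb1a1 was at least 1993-fold lower, with 8 of 10 lung markers lower by both adjustments. For thymus 8 of 11 markers fell by both adjustments, among them the T cell receptor subunit gene Cd3d, at least 322-fold lower. Spleen gave 6 of 10, or 8 adjusted over the list alone. Lamp3 (log2 ratio 0.43, SE 0.72) and Cd8b1 (0.58, SE 0.68) did not pass the test.

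Blood and vessel genes followed the tissues. Myeloid markers fell in 11 of 12 cases, or 12 adjusted over the list alone, with the complement gene C1qc at least 425-fold lower. Endothelial markers fell in 7 of 10 cases, or 8 adjusted over the list alone, with the cadherin gene Cdh5 at least 172-fold lower. Of 10 embryo and erythroid markers 5 fell, or 7 adjusted over the list alone, and the haemoglobin gene Hba-a1 had the lowest log2 ratio among called genes measured on all arrays (-13.21, SE 0.36, limma adjusted p = 0.00846). The sarcomere gene Tnnc2 (-10.52, SE 0.41) and the methyltransferase gene Gnmt (-8.02, SE 0.39) were also lower in 3 of 3 lines.

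**Figure D1:**
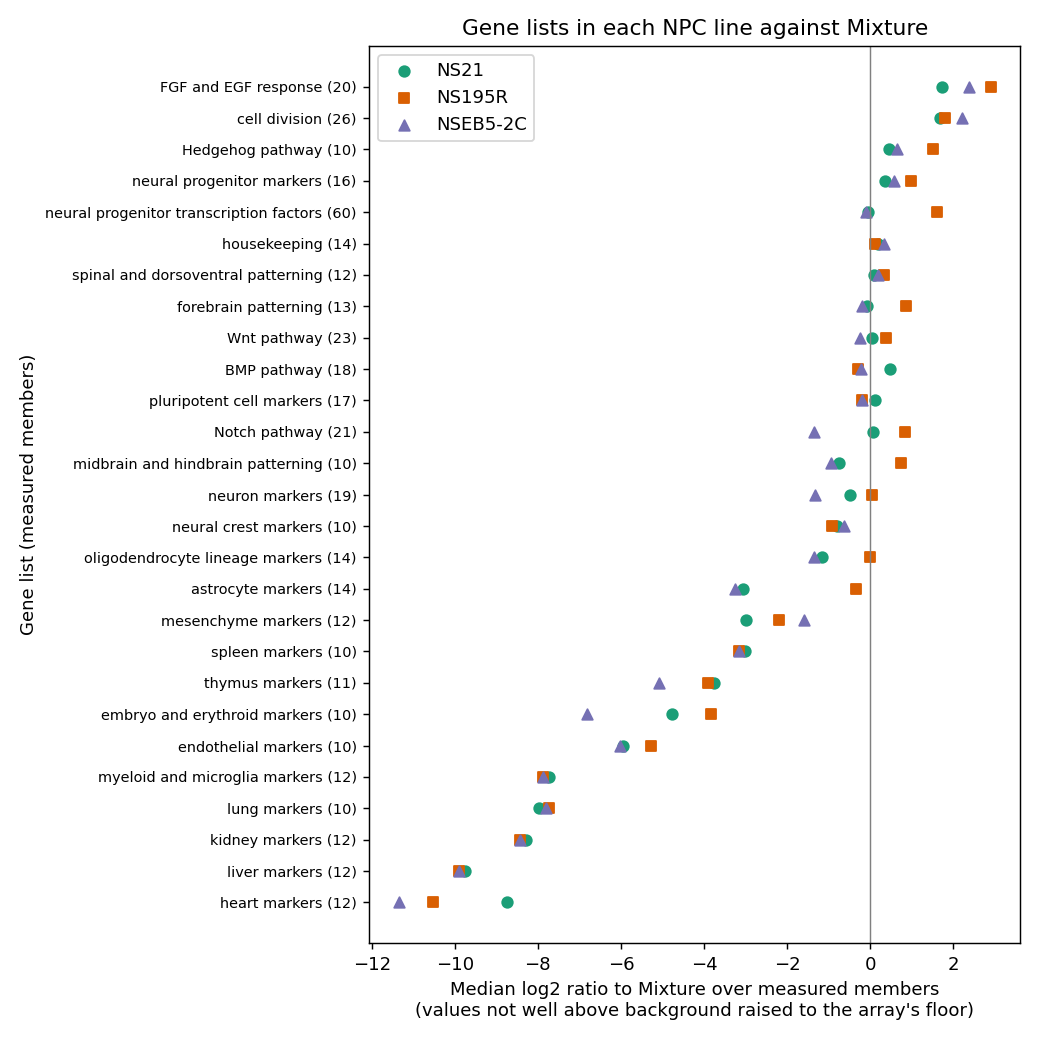
Median log2 ratio to Mixture of each gene list (vertical axis, with its number of measured members) in each NPC line, with 1 array per line and no error bars. Values not well above background are raised to the lowest signal well above background on that array. Liver markers lie at -9.76 in NS21, -9.90 in NS195R and -9.90 in NSEB5-2C, and FGF and EGF response genes at 1.72, 2.91 and 2.39.

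Of the 27 fixed lists, FGF and EGF response genes had the highest median ratio of the NPC lines to Mixture. Etv4, an ETS transcription factor induced by FGF signalling, had a log2 ratio of 6.90 (SE 0.39, limma adjusted p = 0.00926, higher in 3 of 3 lines). The phosphatase gene Dusp4 rose 31.9-fold (SE 0.62 log2, limma adjusted p = 0.0341, higher in 3 of 3 lines), and the signalling inhibitor gene Spry4, not well above background in Mixture, was at least 7.27-fold higher (limma adjusted p = 0.0434, higher in 3 of 3 lines). These were the 3 of 20 FGF and EGF response genes past the test, also when adjusted over the list alone, and 16 of the 20 passed the 1.5-fold rule. The list's median log2 ratio of 2.29 lay at percentile 100 of random lists, whose median was 0.68, and was 1.58 relative to the median shift described with the counts of genes.

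Other called genes higher in 3 of 3 lines were Raet1a (log2 ratio 5.45, SE 0.58), Eps15 (5.42, SE 0.37), the aggrecanase gene Adamts4 (4.19, SE 0.50) and the kinetochore genes Zwilch (3.95, SE 0.44) and Ska3 (3.95, SE 0.36). All 26 cell division genes passed the 1.5-fold rule, and 0 of them passed limma, also adjusted over the list alone, with 19 higher at an unadjusted p under 0.05. The mitotic kinase gene Bub1 lay 8.57-fold above Mixture (SE 0.59 log2, limma adjusted p = 0.0778) and Cdk1 8.27-fold (SE 0.46 log2, limma adjusted p = 0.0509), each in 3 of 3 lines. The list's median of 1.93 lay at percentile 100 of random lists, whose median was 0.84. Housekeeping genes had a median of 0.13, at percentile 1.61 of random lists and -0.58 relative to the median shift. The list's own median was -0.35 with median scaling and 0.50 with the mean of probes. By limma 0 of 14 passed, also adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05.

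In all, limma called 188 genes higher and 1767 lower in the NPC lines, against 3096 and 3050 at an unadjusted p under 0.05. The number higher depended on processing, at 974 with normexp, 587 with quantile normalization, 473 with an intensity trend and 73 with median scaling. Of the lower genes 1524 were not well above background in any line. The calls ended (0 higher and 0 lower) without any 1 of the lines and among genes well above background on all 4 arrays, where 3084 and 710 had an unadjusted p under 0.05. Without a line, between 1499 and 2362 higher and between 2836 and 3391 lower genes had such a p. The median log2 ratio of the 12729 such genes was 0.71, which is more than the 0.58 of the 1.5-fold rule, and relative to it Etv4 lay at 6.19 and the cell division list at 1.22.

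The study asked which transcription factors stand out in NPC lines by the 1.5-fold rule. Tead2, an effector of Hippo signalling, had a log2 ratio of 3.91 (SE 0.43, limma adjusted p = 0.0267) and Foxk2 of 3.03 (SE 0.35, limma adjusted p = 0.0291), both higher in 3 of 3 lines. Hmga2, a chromatin protein of embryonic and stem cells, had 6.55 (SE 2.89), the Hedgehog effector Gli3 had 3.87 (SE 1.22) and Sox9 had 2.89 (SE 0.79), none past limma, with adjusted p of 0.236, 0.150 and 0.125. Not well above background in Mixture were the neural regulators Pax6, at least 9.07-fold higher, and Pax3, at least 7.08-fold higher, neither past limma, with adjusted p of 0.235 and 0.138.

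The rule selected 7149 of 19822 genes and 360 of 985 transcription factors. Of these factors, 8 were called by limma and 49 were not well above background in Mixture. The share of transcription factors selected, 36.5%, was near the 36.8% of the other 14415 named genes (Fisher's exact test, two-sided, odds ratio 0.989, p = 0.891). Random lists matched on level had a median of 31.2% and a highest value of 36.0%, so the 36.5% lay above all of them. The Zfp family, which held zinc finger genes named Zfp, Zfhx, Zfx, Zscan, Zkscan, Zbtb, Zeb or Plag, made up 190 of the 360. It was selected at 55.1% and the other factors at 26.6%, a split chosen after the values were seen. The other factors thus lay below the other named genes (Fisher's exact odds ratio 0.621). With normexp too they lay at 20.1%, against 27.9% of all tested genes. Simulated unchanged lines gave a median of 1974 selected genes. They leave out the median shift against Mixture, 0.71 log2 for genes well above background on all arrays, which is above the rule's 0.58. The 1974 is therefore not a chance level for the 7149. With median scaling the rule selected 4763 genes and 234 factors, and the odds ratio was 0.764 with normexp (Fisher's exact p = 0.000284) and 1.25 with quantile normalization (Fisher's exact p = 0.00107).

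Sox2, a factor of neural stem cells, had a log2 ratio to Mixture of 6.26 in NS195R and 4.44 in NSEB5-2C and was not well above background in NS21, at least 113.5-fold below the other lines. The intermediate filament genes Nes (log2 ratio 2.67, SE 0.95, limma adjusted p = 0.177) and Vim (1.81, SE 0.43, limma adjusted p = 0.103), chosen after their values were seen, lay above Mixture in 3 of 3 lines without passing limma. Of 60 neural progenitor transcription factors, 46 lay at least 1.5-fold above Mixture in NS195R, 20 in NS21 and 23 in NSEB5-2C. With limma 1 of them rose, Tead2, and 0 did so adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05. The list's median of 1.15 lay at percentile 99.99 of random lists. It was 0.52 with normexp, 0.67 with median scaling, 1.50 with quantile normalization and 0.51 with dim genes at their bounds. The 32 members well above background on all 4 arrays had a median of 0.56, below the 0.71 of all such genes. By line the median of the 60 was -0.10 in NS21, 2.05 in NS195R and 0.12 in NSEB5-2C. With dim values raised as in the figure it was -0.06, 1.60 and -0.10, so the list's median rests mostly on NS195R. Of 16 neural progenitor markers 0 passed limma by either adjustment, with 1 higher at an unadjusted p under 0.05, and their median lay at percentile 55.8.

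Markers of other cell types gave few calls. Mesenchyme markers had a median of -2.85 (-2.31 with normexp), at percentile 0 of random lists. Astrocyte markers had a median of -2.13 (-0.38 with normexp), at percentile 0.01. By line the astrocyte median was -3.06 in NS21, -0.34 in NS195R and -3.405 in NSEB5-2C. The low astrocyte median thus rests mostly on NS21 and NSEB5-2C. The tissues pooled in Mixture did not include adult brain, so a low ratio is not evidence that astrocyte expression was lost. Apoe, a lipid carrier gene, fell 32-fold (SE 0.71 log2, limma adjusted p = 0.0447, lower in 3 of 3 lines) as the 1 of 14 astrocyte markers past limma, and 0 of them passed adjusted over the list alone. Neuron markers had 1 of 19 lower, and 0 adjusted over the list alone. For oligodendrocyte lineage (14 genes), pluripotent cell (17), neural crest (10) and mesenchyme (12) markers, 0 passed limma by either adjustment. At an unadjusted p under 0.05 these lists had 0, 0, 1 lower and 2 lower genes. Hedgehog (10 genes), Wnt (23), BMP (18) and spinal patterning (12) genes also had 0 by either adjustment. At an unadjusted p under 0.05, Hedgehog had 2 higher, Wnt 4 higher and 3 lower, BMP 2 higher and 1 lower, and spinal patterning 1 higher. With limma 1 of 21 Notch genes, 1 of 13 forebrain and 2 of 10 midbrain and hindbrain patterning genes fell, by both adjustments.

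Some neural, glial and patterning genes of the fixed lists differed between the lines by large folds, given here as sizes only because each line has 1 array. At least 2-fold above both other lines in NS195R were 8 of 14 astrocyte, 8 of 14 oligodendrocyte lineage and 7 of 16 neural progenitor markers, and 2, 1 and 0 were as far below. So were 9 of 19 neuron markers, 30 of 60 neural progenitor transcription factors and 10 of 21 Notch genes, with 2, 3 and 2 as far below. NS195R held high Fabp7, a radial glia gene, at least 5089-fold above the other lines, the brain proteoglycan gene Bcan, at least 3197-fold, and the oligodendrocyte lineage factors Olig1, at least 1846-fold, and Olig2, at least 747-fold. Lower in NS195R were the myelin gene Mbp, at least 56.1-fold, Cd44, 3.71-fold, and Gja1, 3.17-fold. Among genes measured in all lines, Cspg5 was 241-fold and S100b 179-fold higher in NS195R, while Dusp9 was 348-fold and Rhox5 144-fold lower. NS21 had the highest Pgam2 (751-fold) and Wnt6 (109-fold), and NSEB5-2C the highest Mmp3 (608-fold), with Car2 353-fold lower. Of 17 pluripotent cell markers, 6 lay at least 2-fold above both other lines in NS21 and 1 as far below. In NS195R 1 and in NSEB5-2C 3 lay as far above. In NS21, Lin28a was at least 77.8-fold and Esrrb at least 68.0-fold above the other lines.

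Of 35 Hox genes, which set position along the body axis, 34 were well above background in NS21, 20 in NSEB5-2C and 12 in NS195R. Hoxc6 in NS21 was at least 73.6-fold above the other lines. En2, of the midbrain and hindbrain, was 122.8-fold higher in NS195R than in the other lines.

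**Figure D2:**
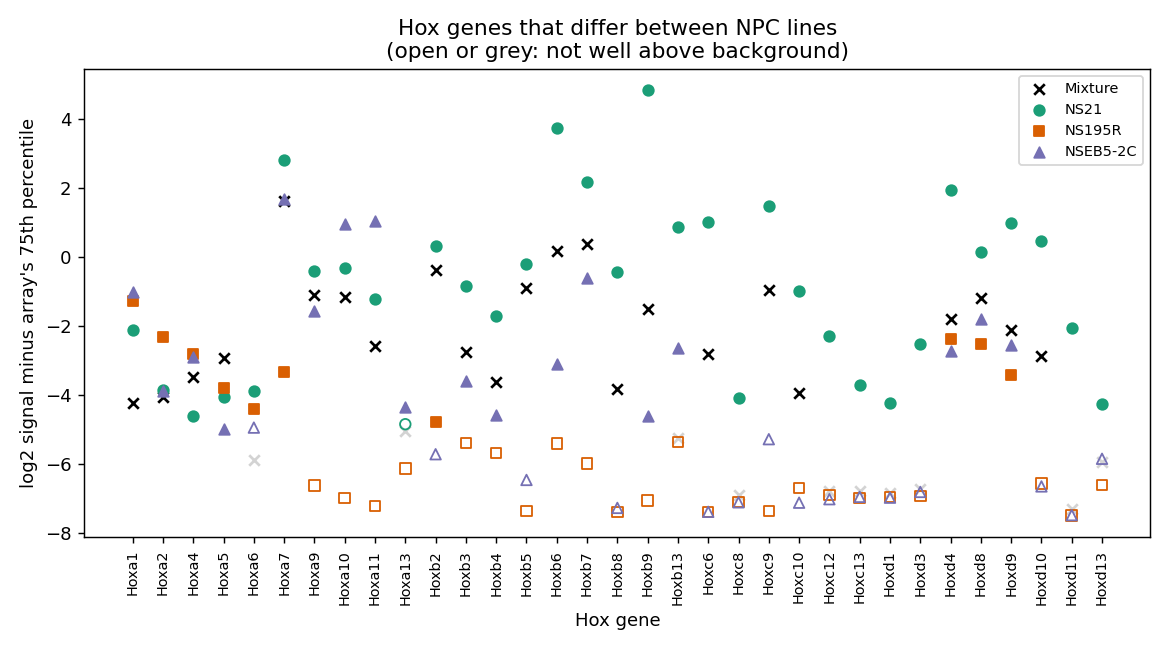
Signal of Hox genes (horizontal axis) that differ between NPC lines, as log2 minus each array's percentile 75, with 1 array per sample and no error bars. Filled or black marks are well above background, and 34 of the 35 measured Hox genes were so in NS21.

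At least 2-fold from both other lines were 1611 genes higher and 953 lower in NS21, 2365 and 1273 in NS195R, and 1297 and 1470 in NSEB5-2C. With dim values raised as in the figure of gene lists, a step added after the values were seen, these were 1447 and 804, 2039 and 1168, and 1111 and 1249. With normexp they were 629 and 381, 1007 and 644, and 592 and 396. In NSEB5-2C more genes were higher than lower with normexp and with quantile normalization (1367 and 1152), the reverse of the first count. Limma called 0 genes for each line, with 1132, 2081 and 1155 at an unadjusted p under 0.05. On simulated data with few genes changed, it called 0 of 50 genes changed in NS195R even at a log2 size of 8. The comparison of lines was not simulated with many genes changed. How many such differences limma would call is therefore not known, and the absence of calls is not evidence against them.

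Across genes, which are not independent replicates, the ratios to Mixture correlated between NS21 and NSEB5-2C at Pearson 0.852 and Spearman 0.775. NS21 and NS195R gave 0.791 and 0.689, and NS195R and NSEB5-2C gave 0.793 and 0.682. The shared Mixture array alone gave a simulated Pearson correlation of 0.498, 0.498 and 0.501 in the order NS21 with NS195R, NS21 with NSEB5-2C and NS195R with NSEB5-2C. For NS21 and NSEB5-2C the covariance was 7.40 against a simulated 1.07. These lines shared 6475 genes at least 1.5-fold above Mixture, where simulated unchanged lines with the same Mixture array shared a median of 1378 and independent lists would share 3599.5. The first of these leaves out real effects and the second leaves out the common Mixture array, which could not be split, so the excess over either is not a measure of shared effects.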

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

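Some genes lay at least 4-fold above Mixture in 1 NPC line and at least 4-fold below it in another, with values not well above background raised to the lowest signal well above background on that array, and these differences were not tested, since each line has 1 array. The log2 difference between the highest and the lowest line was at least 12.38 for Fabp7 and 11.71 for Bcan, both highest in NS195R. Measured in all lines were Bmp4 (5.27) and Msx1 (5.99), highest in NS21, and Twist2 (5.13), highest in NSEB5-2C. It was at least 6.17 for Esrrb and 7.43 for Fzd10, highest in NS21. Among Hox genes it was at least 6.15 for Hoxa10 and 6.24 for Hoxa11, highest in NSEB5-2C, and at least 8.95 for Hoxb6, 10.05 for Hoxb9, 6.20 for Hoxc6, 6.69 for Hoxc9 and 5.66 for Hoxd10, highest in NS21.

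The tests of the genes higher in NS195R were set before their results were seen. Carried-over Mixture or tissue RNA was argued against as the whole cause. Dim values were raised in the same way, a step added after the first result. The 2365 genes then had a median log2 ratio to Mixture 8.82 above that of the tissue markers in NS195R, of which 17 of 67 were well above background there. Of the 2365 genes, 74.2% lay above the Mixture level, and the test does not decide for the others. Scaling was argued against as the whole cause, since 2198 genes remained in number with quantile normalization. Strain and culture state of the line cannot be told apart, because only 1 NPC array, NS195R itself, has its strain label.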

How the results depend on the processing

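The alternatives that count transcription factors without the Zfp family, and genes apart with dim values raised to the lowest signal well above background, were chosen after seeing the data. No paired analysis was possible because Mixture has 1 array. Genes higher in the NPC lines numbered 974 with normexp, 587 with quantile normalization, 73 with median scaling, 525 without a filter, 473 with an intensity trend and 0 among genes well above background on all 4 arrays, against 188. The share of calls that were higher was 32.9% with normexp, 26.5% with quantile normalization, 21.1% without a filter and 3.71% with median scaling, against 9.62%. Genes lower and list members past the test both numbered 0 among genes well above background on all 4 arrays. Leaving out each line in turn gave 0 higher genes, 0 lower genes and 0 list members every time, with 1 residual degree of freedom fewer. The 1.5-fold rule selected 4763 genes and 234 transcription factors with median scaling, and 170 factors without the Zfp family. The mean correlation of the ratios was 0.812, 0.729 among genes well above background on all 4 arrays, and between 0.791 and 0.852 without 1 line. Genes apart numbered 1010 in NS21, 1651 in NS195R and 988 in NSEB5-2C with normexp, 1195, 1704 and 1401 among genes well above background on all 4 arrays, and 2251, 3207 and 2360 with dim values raised. In NSEB5-2C the genes higher outnumbered those lower with normexp (592 and 396), with quantile normalization (1367 and 1152) and in no other setting. The other alternatives kept these counts within 1.5-fold, and the deposited value table gave identical values. Of 58 named genes past the test, 55 stayed so with normexp, 58 with quantile normalization, 57 with median scaling, 52 without a filter and 50 with the mean of probes. The median log2 ratio of genes well above background on all arrays was 0.53 with normexp, 0.74 with quantile normalization and 0.22 with median scaling, against 0.71. The cause of these differences was not tested. Of the 1767 lower genes, 1524 were not well above background in any line, so that their ratios are only bounds.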

Other observations

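The genes and tests here were chosen after the values were seen, except for the splits of chromosome 14 by signal level and by position. Hprt had log2 levels of 4.03 in Mixture and 3.33 in NS195R, and of -2.40 in NS21 and -1.29 in NSEB5-2C, the lines that share a strain label. The Y-linked genes Ddx3y and Eif2s3y were not well above background in NS21 and were so in the other lines. Xist, well above background in Mixture, was not so in any NPC line. Among genes well above background in all 3 lines, the 371 of chromosome X had a median log2 ratio to Mixture of 1.18, and the medians of the autosomes lay between 0.53 and 0.99. Over all tested genes with a known chromosome these were 0.90, for 552 genes of chromosome X, and between 0.02 and 0.57. The ribosomal protein gene Rps6 was 125-fold lower in NS21 than in the other lines, and the chromosome 15 genes Eef1d and Pycrl 108-fold and 139-fold lower. A run of neighbouring genes around these 2 is not reported, because its genes Gsdmd and Tigd5 were not well above background in NS21 and their differences are not bounded at 4-fold. The tests made of that run are left out.

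Genes of chromosome 14 were lower in NSEB5-2C than in the other lines, by a median of -0.49 log2 relative to other autosomes over 377 genes well above background in all 3 lines. A bias with signal level was argued against, since the shift was -0.38, -0.67 and -0.41 in 3 classes of level. Random sets of genes gave a median as low in 0% of 10000 draws, which leaves out that neighbouring genes can be regulated together. Whole chromosomes varied more than such sets, whose lowest median was -0.087. The median of NSEB5-2C minus the other lines lay between -0.12 (chromosome 10) and 0.26 (chromosome 3) for other autosomes, against -0.42 for chromosome 14. Since chromosome 14 was picked for its low values, the draws do not measure how often a chromosome lies this low. The share of genes below the median of other autosomes was 50%, 89.6% and 76.2% in 3 successive parts of the chromosome, so the shift was not seen over the whole chromosome and a change in 1 segment stays open. No biological explanation was tested.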
